A study of Mus musculus with 11 samples.

How the data were processed

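Lungs of male C57BL/6 mice aged 12 to 13 weeks were dissociated with collagenase on day 11, viable cells were loaded on a Chromium instrument, and 3′ libraries of version 2 chemistry were sequenced on an Illumina NextSeq500 with 59 bp of transcript, per the labels' protocols. Bleomycin was dosed at 2.8 U/kg (1.75 mg/kg) or saline in its place, nintedanib at 60 mg/kg, and the vehicle was 0.5% carboxymethyl cellulose, per the labels. The series' design text places bleomycin in the mouth near the larynx, whereas the treatment label speaks of oral gavage for all compounds; the design text was followed. Groups and replicate numbers were taken from the sample labels. The deposited values are UMI counts per gene and barcode, 1 matrix for each library, which the authors made with Cell Ranger 2.0.0 on mm10, per the submitters' processing notes. Their filters on barcodes are not given in the sources used here, and no deposited cell annotation was used. The matrices hold 25127 rows, of which 27 are construct sequences with 188 UMIs in all; the other rows carry gene symbols with a chromosome and strand, and 631 rows that share a symbol were summed, leaving 24469 symbols. Genes that share sequence with close copies can trade reads in such counts.

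Everything below was computed from these counts. Barcodes with under 200 genes or over 20% mitochondrial UMIs were left out (282), and doublets were scored with Scrublet in scanpy, the highest-scoring 0.8% for each 1000 barcodes of a library being removed (263, or 1.41%). Cells were normalized to their totals and log-transformed, reduced to 30 principal components of 2000 variable genes, joined in a graph of 15 neighbours and clustered with Leiden at resolution 1, with no batch integration. A cluster was named when at least 3 of its 50 leading genes were markers of 1 class fixed before the data were examined, and stayed unnamed if its 10 leading genes held more markers of another class, if 5 or more of the 50 were markers of a second class, if over 90% of it came from 1 library, or if its depth was low against its libraries and no marker was among the 10. Leading genes were ranked by fold with a pseudocount of 50 CPM. That value was chosen over 10 and 100 CPM after the leading genes of clusters, but no comparison of groups, had been seen, and a minimum of 10% of cells with Ptprc for leukocyte names was added after a cluster of 26 adipocyte-like cells had been named alveolar macrophage. Of the 46 clusters 35 were named, in 20 classes, and 1934 cells (10.5%) stayed unnamed. Unnamed clusters included thymocyte-like cells almost all of saline replicate 4, plasma cells mostly of saline replicate 2, neutrophil-like cells with Saa3 and Il1r2, ciliated and secretory cells, and mixtures of endothelial cells with pericytes or neutrophils.

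Shares are percent of retained cells per library, compared by exact two-sided permutation tests in which the p is 2 times the smaller tail. For gene tests the counts of each class were summed per library where it had at least 10 cells, filtered with filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood F-test over all 3 groups in 1 fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. A standard error is the absolute log2 fold change over the square root of F. CPM values are means over libraries. The main classes were fibroblast, alveolar macrophage, interstitial or monocyte-derived macrophage, vascular endothelial and alveolar type 2. Gene lists, 22 in all, were fixed before the data were examined and tested with limma's fry and camera on voom values, camera with a preset correlation of 0.01 and also with an estimated one. For these tests the difference between 2 groups was coded as a coefficient of the model, since an earlier coding as a contrast gave values of fry and of the estimated correlation that depended on rounding; this was changed after results had been seen, and the same lists passed camera in both forms. They were extracellular matrix, contractile, TGF-beta response, resting alveolar fibroblast, PDGF FGF and VEGF receptors and ligands, MAP kinase feedback, cell cycle, p53 targets, interferon response, inflammatory mediators, secretory pathway and unfolded protein, glycolysis, dissociation and immediate early, MHC class II, macrophage fibrosis-associated, alveolar macrophage homeostasis, lipid handling, endothelial activation, endothelial tip cell, capillary identity, surfactant and transitional epithelial. For activation transcripts each fibroblast-like cell was thinned to 1000 UMIs; no cell was below that depth.

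The genes named were set by a rule fixed before the data were examined. For each comparison it took up to 10 called genes with the largest rise and 10 with the largest fall in fibroblast-like cells and 5 and 5 in the other main classes, with a mean of at least 50 CPM in a group and no overlap between libraries, leaving out naming markers of other classes, mitochondrial, ribosomal protein, immunoglobulin, T cell receptor, haemoglobin and clone-named genes. Up to 4 members of each list with the smallest p were added, and 12 genes were always given in fibroblast-like cells: Col1a1, Acta2, Cthrc1, Tnc, Postn, Spp1, Timp1, Pdgfra, Pdgfrb, Fgfr1, Tgfb1 and Ctgf. Other classes got at most 3 each way. The text gives those taken by the rule that the comparisons turn on. Gene positions come from GENCODE's GRCm38 annotation, matched by symbol; chromosome and strand in the deposited row names were the same for the 11 genes looked up.

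Median depth per cell was 3433 to 7714 UMIs by library. Fibroblast-like cells numbered 108 to 244 per library. Bleomycin libraries were on average deeper per fibroblast-like cell than saline ones, which thinning addresses for shares of cells and scaling for CPM. No pair of libraries of a group agreed within sampling noise (chi-square over degrees of freedom 1.84 to 16.9 in 15 pairs), and no pair of libraries shared more than 10 barcodes. Each test was tried on simulated counts with 200 genes changed, of which those passing the filter were scored. In fibroblast-like cells, bleomycin against saline, 81.4% of 4-fold and 24.5% of 2-fold changes were recovered over 9080 genes, with 7.21% false calls. For nintedanib against bleomycin the values were 84.8%, 21.4% and 4.55% over 9130 genes. Recovery of 4-fold changes in the same comparisons was 94.9% and 89.8% in alveolar macrophage-like, 72.4% and 91.8% in interstitial or monocyte-derived macrophage-like, 88.7% and 85.7% in vascular endothelial-like and 83.9% and 77.1% in alveolar type 2-like cells. False calls in the same order were 5.47% and 4.17%, 3.45% and 11.8%, 7.14% and 7.56%, and 6.48% and 4.44%.

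Alternatives fixed before the data were examined were DESeq2, its size factors, no filter on low counts, only the groups compared, the replicate number as a block, the number series in the sample titles as a covariate, a stricter cell filter (500 genes, 10% mitochondrial), no doublet removal, Leiden resolution 2, at least 30 cells, a filter against free RNA, thinning to 2000 UMIs or none, and leaving out each library. Chosen after the data were seen were the sets of libraries A and B, the exclusion of the libraries with many neutrophils (saline replicate 2 and nintedanib replicate 3) and the other naming pseudocounts. The sets came from splits of the libraries that called many genes in 3 classes. Some genes are not reported here. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.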

Results

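Single cells from the lungs of male C57BL/6 mice were profiled on day 11 after a dose of bleomycin, a DNA-damaging drug that injures the lung and is used to induce lung fibrosis in mice, or of saline. Bleomycin was given at 2.8 U/kg into the mouth near the larynx. The series compared 3 groups, with 4 saline libraries, 4 bleomycin libraries and 3 libraries of bleomycin plus nintedanib, an inhibitor of the PDGF, FGF and VEGF receptor tyrosine kinases, given at 60 mg/kg daily from the time of bleomycin. Its stated purpose was to define the activated fibroblast population. The deposited matrices held 18975 barcodes and 133731791 UMIs, with 7337326 to 11914428 UMIs per saline library, 8668359 to 18987009 per bleomycin library and 8360150 to 18179655 per nintedanib library. Of these barcodes 18430 were retained, 1570 ± 313 per saline library (SD, n = 4), 1749 ± 216 per bleomycin library (SD, n = 4) and 1719 ± 529 per nintedanib library (SD, n = 3). The labels do not state in so many words that each library came from a different mouse, so p-values measure the spread between these samples.

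The 46 clusters gave 20 cell classes, named by markers and called here by the class they resembled. Fibroblast-like cells fell mainly into 4 clusters. One was led by Eln, Timp1 and Col1a1 and held 3.57% to 10.5% of the class in the saline libraries, 59.0% to 79.9% in the bleomycin libraries and 91.8%, 57.4% and 25.2% in nintedanib replicates 1 to 3. One led by Gpx3, Mt2 and Serpina3n held 69.6% in saline replicate 2 and 56.4% in nintedanib replicate 3, and at most 0.909% in any other library. A cluster led by Inmt, Gsn and Mfap4 held 0.893% in saline replicate 2 and 60.5% to 75.5% in the other saline libraries, 2.87% to 28.2% in the bleomycin and 0% to 17.6% in the nintedanib libraries. One led by Pi16, Clec3b and Dcn held 16.0% to 28.5%, 12.8% to 25.4% and 4.79% to 25.0%. Values within this class therefore compare mixtures of clusters that differ between groups. The same holds for the interstitial or monocyte-derived macrophage-like class, in which a cluster led by Ccl8, C1q genes and Folr2 held 45.3% to 83.6% in the saline and 14.7% to 48.0% in the bleomycin libraries, and one led by Gpnmb, Spp1 and Trem2 held 0% to 20% and 24.1% to 53.2%. It also holds for the vascular endothelial-like class. There a cluster led by Gpihbp1, Tmem100 and Egfl7 held 0% in saline replicate 2, 39.2% to 58.6% in the other saline libraries and 61.9% to 74.5% in the bleomycin libraries, and one led by Car4, Cldn5 and Ly6c1 held 35.1% to 73.5% in saline and 12.7% to 26.8% in bleomycin libraries. Cells of unnamed clusters made up 19.6% ± 12.2 of saline (SD, n = 4), 3.84% ± 0.666 of bleomycin (SD, n = 4) and 8.67% ± 9.46 of nintedanib libraries (SD, n = 3).

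The libraries also differed in a way the groups did not explain. A set of 72 genes was lower in every class scored in saline replicates 1 and 2, bleomycin replicates 1 and 2 and nintedanib replicate 1 (called set A here) than in the other 6 libraries (set B). The genes were found in fibroblast-like, vascular endothelial-like and interstitial or monocyte-derived macrophage-like cells, and the libraries were divided by their levels in T-like and B-like cells. In alveolar type 1-like and mesothelial-like cells, which served for neither, their mean log2 CPM was 5.25 and 5.07 in set A and 6.73 and 6.44 in set B. Tgfb1 was among the 72 genes. The labels give no preparation or sequencing batch. Each group had libraries in both sets, so shares, calls and fold changes of leading genes are also given within each set, where libraries are fewer. Of 122 called results for genes taken by the naming rule, bleomycin against saline, 19 kept their call within set A and 71 within set B. Nintedanib against saline 10 of 32 did in set B, and set A holds 1 nintedanib library. None changed sign.

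**Figure D1:**
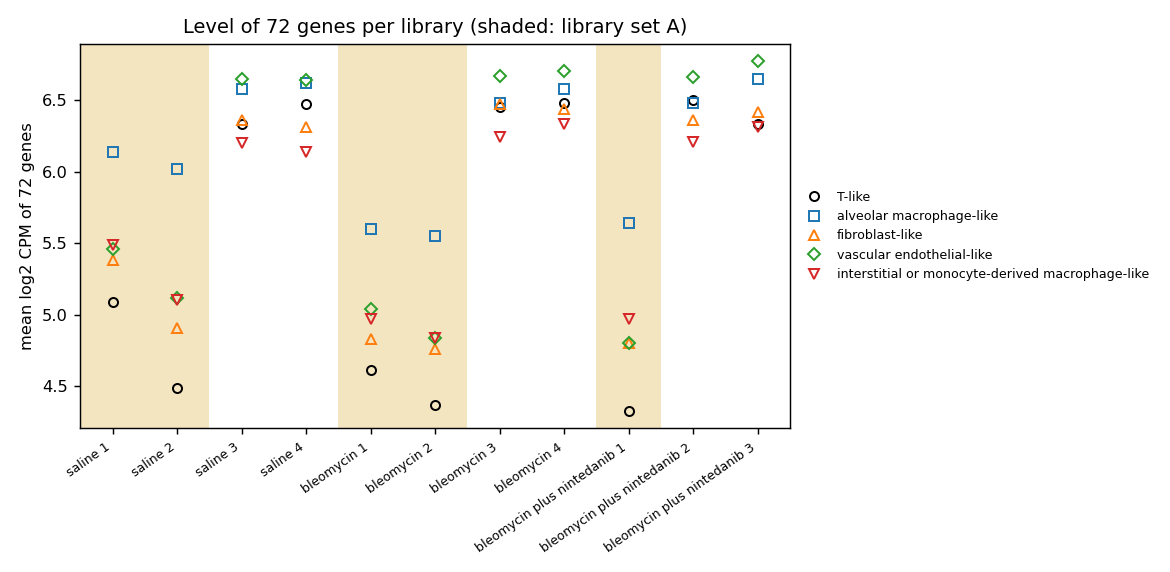
Mean log2 CPM of the 72 genes for each of the 11 libraries in 5 cell classes, with the libraries of set A shaded. T-like cells were used to divide the libraries and the last 3 classes to find the genes. In alveolar macrophage-like cells, used for neither, the means were 5.79 and 6.57.

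Macrophage-like cells outside the alveolar macrophage class made up a larger share of bleomycin than of saline lungs. Interstitial or monocyte-derived macrophage-like cells were 27.6% ± 9.58 of retained cells in bleomycin libraries and 4.86% ± 1.28 in saline libraries (SD, n = 4 each). Mature dendritic-like cells were 2.44% ± 0.442 against 0.581% ± 0.206, plasmacytoid dendritic-like cells 0.487% ± 0.0293 against 0.169% ± 0.144, and proliferating cells 3.32% ± 1.62 against 0.768% ± 0.501. The share of alveolar type 2-like cells, which make surfactant, was 2.05% ± 0.712 against 9.78% ± 6.65, and that of fibroblast-like cells was 10.5% ± 2.50 against 10.4% ± 3.15. Alveolar macrophage-like cells made up 5.06% ± 2.56 against 3.83% ± 2.23, and vascular endothelial-like cells 9.34% ± 3.03 against 7.46% ± 4.31. For the first 4 classes no bleomycin library overlapped a saline library, and the exact two-sided permutation test gave p = 0.0286, the smallest that 70 assignments allow. Adjusted over 20 classes this was 0.143, so no class passed an adjusted threshold of 0.05. The same exact permutation test gave p = 0.0571 for alveolar type 2-like cells, 0.971 for fibroblast-like, 0.486 for alveolar macrophage-like and 0.486 for vascular endothelial-like cells.

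Within the sets of libraries, interstitial or monocyte-derived macrophage-like cells were 14.1 percentage points higher with bleomycin in set A and 31.4 points higher in set B (n = 2 against 2 in each). Alveolar type 2-like cells differed by −2.70 points in set A and −12.7 in set B. The difference took opposite signs in the 2 sets for fibroblast-like (0.842 and −0.662 points), alveolar macrophage-like (−0.787 and 3.24) and vascular endothelial-like cells (4.02 and −0.257). Leaving out saline replicate 2, in which 31.4% of cells were neutrophil-like, gave a fibroblast-like difference of −0.840 points in place of 0.0901.

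With nintedanib, interstitial or monocyte-derived macrophage-like cells made up 25.9% ± 3.55 (SD, n = 3) against 27.6% with bleomycin alone, and fibroblast-like cells 9.36% ± 3.58 against 10.5%. Conventional dendritic-like cells of type 1 made up 2.18% ± 0.592 against 3.68% ± 0.989, and mature dendritic-like cells 1.54% ± 0.892 against 2.44%. Alveolar macrophage-like cells were 6.77% ± 2.91, vascular endothelial-like cells 8.10% ± 3.27 and alveolar type 2-like cells 1.86% ± 0.917 of cells (SD, n = 3). The lowest p of the exact two-sided permutation test over the 20 classes was 0.114, adjusted 0.571. With 4 against 3 libraries the smallest possible p is 0.0571, so this comparison could not reach 0.05. Within sets the fibroblast-like difference was 2.64 points in set A, with 1 nintedanib library, and −3.19 in set B, and that of interstitial or monocyte-derived macrophage-like cells 6.04 and −9.37. It was 4.86 and −0.876 points for alveolar macrophage-like, −1.51 and 0.589 for alveolar type 2-like and 0.318 and −1.02 for vascular endothelial-like cells, so all 5 differed in sign between the sets.

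**Figure D2:**
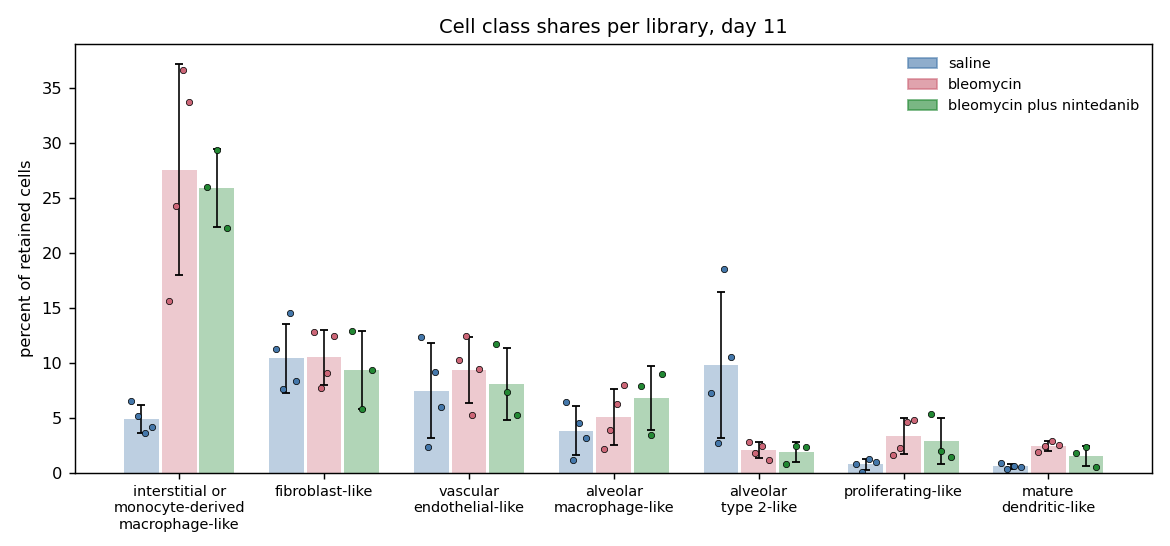
Percent of retained cells in 7 cell classes for each library, with points for libraries, bars for group means and error bars for the SD. Interstitial or monocyte-derived macrophage-like cells lie between 15.6% and 36.7% in the bleomycin libraries, above the highest saline library at 6.56%.

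The activated fibroblast, the subject of the series, was addressed by comparing fibroblast-like cells of bleomycin and saline lungs. Genes for secreted matrix and matricellular proteins rose. Col1a1, which encodes a chain of type I collagen, rose from 739 ± 157 to 2820 ± 911 CPM (SD, n = 4 each), a log2 fold change of 1.93 (SE 0.32, edgeR adjusted p = 0.0103). Ltbp2, a matrix protein related to the latent TGF-beta binding proteins, rose from 13.1 ± 8.76 to 353 ± 121 CPM (4.62, SE 0.50, adjusted p = 0.00192), and Timp1, an inhibitor of metalloproteinases, from 118 ± 95.8 to 1550 ± 319 CPM (3.76, SE 0.55, adjusted p = 0.00683). Ccl2, a chemokine that attracts monocytes, rose from 3.52 ± 3.64 to 155 ± 95.0 CPM (5.05, SE 0.71, adjusted p = 0.00585). Igfbp3, which encodes a binding protein of insulin-like growth factors, fell from 212 ± 43.3 to 14.3 ± 1.46 CPM (−3.87, SE 0.37, adjusted p = 0.00117). Gria1, a glutamate receptor subunit, fell by 3.06 on the log2 scale (SE 0.49) and Faim2 by 2.67 (SE 0.40). All 7 of these genes kept their call in each of the 8 fits that left out 1 library. Within sets A and B (n = 2 against 2 in each) the log2 fold change was 1.38 and 2.38 for Col1a1, 3.87 and 5.54 for Ltbp2, 3.20 and 4.82 for Timp1, 5.22 and 4.61 for Ccl2, −3.93 and −3.83 for Igfbp3, −2.51 and −3.56 for Gria1 and −2.03 and −3.30 for Faim2. Col1a1, Gria1 and Faim2 lost their calls in set A.

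Among the other genes with the largest called rises were Spp1 (osteopontin) with a log2 fold change of 7.24 (SE 1.41, 26.2 ± 50.7 to 2930 ± 2580 CPM), Cthrc1 with 4.90 (SE 1.1, 9.28 ± 12.9 to 201 ± 143 CPM), Tnc (tenascin C) with 4.85 (SE 0.86), Wisp1 with 4.27 (SE 0.77), Postn (periostin) with 4.13 (SE 0.91, 8.16 ± 8.5 to 173 ± 148 CPM) and Inhba with 3.68 (SE 0.74). Acta2, the smooth muscle actin of myofibroblasts, rose from 92.9 ± 49.5 to 767 ± 551 CPM (3.08, SE 0.74, adjusted p = 0.0417). Further called falls were those of Inmt, a methyltransferase of resting lung fibroblasts, from 8950 ± 1670 to 1660 ± 903 CPM (−2.43, SE 0.46), the actin-severing gelsolin gene Gsn (−2.48, SE 0.48), Txnip (−2.67, SE 0.55) and Il6ra (−2.44, SE 0.53), with Tsc22d3 (−2.42, SE 0.59) and Klf15 (−2.38, SE 0.60), which glucocorticoids induce. Their edgeR adjusted p-values ran from 0.0150 (Tnc) to 0.0483 (Klf15), and these calls depended on single libraries. The calls of Tnc, Wisp1 and Inmt were lost without saline replicate 3 or 4, those of Spp1 and Inhba also without bleomycin replicate 4, that of Txnip without bleomycin replicate 2, 3 or 4, and that of Gsn without any of these 3 or saline replicate 4. Il6ra lost its call without bleomycin replicates 2, 3 or 4 or saline replicates 3 or 4, Cthrc1 also without saline replicate 1, and Postn without any saline library or bleomycin replicate 3 or 4. Acta2 kept it only without bleomycin replicate 1, Klf15 only without saline replicate 1 and Tsc22d3 in none of the 8 fits. Over these fits the log2 fold change stayed between 6.48 and 11.3 for Spp1, 4.4 and 5.96 for Cthrc1, 4.56 and 5.95 for Tnc, 3.38 and 4.84 for Postn, 2.44 and 3.45 for Acta2, −2.81 and −2.15 for Inmt, −2.80 and −2.23 for Gsn, −2.97 and −1.66 for Txnip, −2.71 and −1.58 for Tsc22d3 and −2.70 and −1.80 for Klf15. By library set, A then B, it was 5.76 and 11.4 for Spp1, 2.68 and 7.88 for Cthrc1, 3.79 and 6.15 for Tnc, 2.95 and 4.59 for Postn, 2.52 and 3.47 for Acta2 and −1.78 and −3.23 for Inmt. None of the genes of this paragraph was called in set A, and Postn, Acta2, Txnip, Tsc22d3 and Klf15 were not called in set B.

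In GRCm38 (mm10), the build of the deposited matrices, Col1a1 spans 94936224 to 94953042 on chromosome 11, Acta2 34241090 to 34255590 on chromosome 19, Cthrc1 39076932 to 39087121 on chromosome 15, Tnc 63959785 to 64047015 on chromosome 4, Postn 54361109 to 54391037 on chromosome 3, Spp1 104435118 to 104441050 on chromosome 5 and Timp1 20870166 to 20874735 on chromosome X. The positions are those of the whole gene in the annotation, and 3′ libraries count reads near transcript ends, exons not being told apart.

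Of the genes tested in fibroblast-like cells (9284), edgeR called 362 with bleomycin, 197 higher and 165 lower. The count fell to 140 without bleomycin replicate 2, 141 without replicate 3, 74 without replicate 4, 81 without saline replicate 3 and 68 without saline replicate 4. DESeq2 called 737, and within sets edgeR called 6 genes in set A, among them Ltbp2, Timp1, Ccl2 and Igfbp3, and 221 in set B.

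Many matrix genes rose. Of 28 extracellular matrix genes 17 rose and 1, Ecm1, fell (22 and 1 adjusted over the list alone). Besides those named, they included Col5a2 (112 to 677 CPM, log2 fold change 2.59, SE 0.34), fibronectin Fn1 (520 to 2980 CPM, 2.52, SE 0.35) and Sparc (1900 to 6680 CPM, 1.82, SE 0.26). Of 14 contractile genes 5 rose (9 adjusted over the list alone), among them Acta2 and Actn1 (1.95, SE 0.44), an actin crosslinker. The camera test gave adjusted p = 1.9e-14 for the matrix list and 5.09e-08 for the contractile list, and adjusted p = 0.248 and 0.293 with an estimated correlation. Of 17 TGF-beta response genes 1 rose, while Bambi, a decoy receptor (85.5 to 36.0 CPM, −1.25, SE 0.22), and Igfbp3 fell (3 and 4 adjusted over the list alone). That list did not move one way (camera adjusted p = 0.802). Fry for change in either direction passed for 12 of the 14 fibroblast-like lists, this one included (adjusted p = 2.31e-05). Of 18 resting alveolar fibroblast genes Inmt fell and Lpl, which hydrolyses triglycerides, rose (1.12, SE 0.28). Adjusted over the list alone 2 fell and 1 rose, with camera adjusted p = 0.0269 toward lower levels, and adjusted p = 0.619 with an estimated correlation. Lpl was lost in each fit that left out 1 library (0.93 to 1.24), and Actn1 without saline replicate 3 or 4 or bleomycin replicate 2, 3 or 4 (1.67 to 2.15).

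Targets of p53, the transcription factor that responds to DNA damage, rose together. Of 15 tested, 7 were called higher and none lower (10 and 0 adjusted over the list alone), including the pro-apoptotic Bax from 113 ± 24.0 to 298 ± 28.3 CPM (1.40, SE 0.20), Ccng1 (1.14, SE 0.19), Aen (1.46, SE 0.24) and Zmat3 (1.56, SE 0.27), each called in all 8 fits that left out 1 library. Taken by set, A then B, the values were 1.29 and 1.53 for Bax, 1.07 and 1.21 for Ccng1, 1.39 and 1.56 for Aen and 1.40 and 1.66 for Zmat3, with no call in set A and all but Ccng1 called in set B. The p53 list was the only fibroblast-like list past the threshold in both forms of camera (adjusted p = 3.22e-09, and adjusted p = 0.0139 with an estimated correlation). Of 23 interferon response genes 6 rose (13 adjusted over the list alone), including the nucleic acid sensor Zbp1 from 11.4 to 70.3 CPM (2.93, SE 0.44) and the GTPase Iigp1 from 44.4 to 167 CPM (1.91, SE 0.32). Of 21 inflammatory mediators 3 rose (5 adjusted over the list alone), with Ccl2 and the chemokine Cxcl12 (290 ± 54.0 to 737 ± 78.1 CPM, 1.35, SE 0.18). Camera gave adjusted p = 5.09e-08 and 0.00972 for these lists, and adjusted p = 0.293 and 0.336 with an estimated correlation. Bleomycin replicate 1 stood above the other bleomycin libraries for Zbp1 (102 CPM against at most 62.3). Without it 18 of 22 interferon response genes were higher (camera adjusted p = 1.43e-06, and adjusted p = 0.322 with an estimated correlation).

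Immediate early genes, which dissociation of tissue also induces, went the other way. Fos (−1.42, SE 0.36), Zfp36 (−1.44, SE 0.32) and Nr4a1 (−1.84, SE 0.45) fell among 19 tested (0 higher and 12 lower adjusted over the list alone; camera adjusted p = 1.77e-07, and adjusted p = 0.293 with an estimated correlation). Their calls depended on single libraries. Fos lost its call in each fit that left out 1 library (−1.60 to −1.16), Nr4a1 in all but the one without saline replicate 2 (−2.07 to −1.37), and Zfp36 without saline replicate 2 or 4 or bleomycin replicate 2, 3 or 4 (−1.62 to −1.27). Of 20 secretory pathway genes 2 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 4.42e-05, and adjusted p = 0.336 with an estimated correlation). Of 15 cell cycle genes 1 rose (1 adjusted over the list alone; adjusted p = 0.0341, and adjusted p = 0.619 with an estimated correlation). Camera did not pass for 14 glycolysis genes (1 higher, 1 lower, also adjusted over the list alone; adjusted p = 0.676), 14 MAP kinase feedback genes (1 higher; 1 and 1 adjusted over the list alone; adjusted p = 0.802) or 6 MHC class II genes (none called, also adjusted over the list alone; adjusted p = 0.802).

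Receptors that nintedanib inhibits were measured in the same cells. Of 14 PDGF, FGF and VEGF receptors and ligands none rose, and Fgfr3 (−1.24, SE 0.28) and Fgf7 (−1.21, SE 0.28) fell (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.971). Fgfr3 lost its call without saline replicate 3 or 4 or bleomycin replicate 2, 3 or 4 (−1.39 to −1.1), and Fgf7 without any of these or saline replicate 2 (−1.39 to −1.09). The log2 fold change was −0.85 for Pdgfra (680 to 377 CPM, SE 0.31, edgeR adjusted p = 0.128), 0.67 for Pdgfrb (adjusted p = 0.38) and −0.33 for Fgfr1 (adjusted p = 0.403). Tgfb1 (1.24, SE 0.90, adjusted p = 0.447) and Ctgf (1.5, SE 0.54, adjusted p = 0.124) were not called either. Tgfb1, one of the 72 genes, stood at 0.14 and 1.40 within sets A and B.

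Activation transcripts were also counted per cell, after each fibroblast-like cell was thinned to 1000 UMIs. Acta2 was seen in 16.9% ± 8.03 of cells with bleomycin and 5.31% ± 2.14 with saline (SD, n = 4 each), Cthrc1 in 6.34% ± 5.78 and 0.110% ± 0.219, Tnc in 12.5% ± 5.04 and 0.447% ± 0.621, and Postn in 6.44% ± 5.23 and 0.678% ± 0.453. Col1a1 was seen in 69.4% ± 9.12 and 38.9% ± 12.5, Timp1 in 35.1% ± 7.84 and 8.26% ± 6.47, and Spp1 in 9.0% ± 6.39 and 0.223% ± 0.446. All 7 rose without overlap between the libraries, each at p = 0.0286 in the exact two-sided permutation test, the smallest possible, and adjusted 0.0286 over the 7 genes. In T-like cells, which should lack these transcripts, the highest group mean was 1.01% of thinned cells (Spp1 with bleomycin), and the highest single library had 2.61%. Median depths were 4294 UMIs in saline and 7750 in bleomycin fibroblast-like cells, and 3188 and 3544 in T-like cells. Without thinning, the shares with bleomycin and saline were 40.1% and 13.1% for Acta2, 17.4% and 2.12% for Cthrc1 and 94.0% and 73.4% for Col1a1. The test on Col1a1 then gave p = 0.0857 (exact permutation). With nintedanib the thinned shares were 15.3% ± 14.8 for Acta2, 4.56% ± 5.01 for Cthrc1, 9.84% ± 9.49 for Tnc, 4.47% ± 3.43 for Postn, 66.4% ± 10.4 for Col1a1, 41.8% ± 10.5 for Timp1 and 11.4% ± 4.60 for Spp1 (SD, n = 3). Against bleomycin the exact permutation test gave p from 0.457 to 0.8 (smallest possible 0.0571). In set B (n = 2 each) shares with nintedanib and bleomycin were 6.86% and 19.2% for Acta2 and 1.70% and 10.9% for Cthrc1. They were 4.48% and 15.2% for Tnc and 2.59% and 9.93% for Postn. None of these overlapped, unlike Col1a1, Timp1 and Spp1. In set A the 1 nintedanib library lay above both bleomycin ones for all 7 (32.2% against 14.7% for Acta2, 10.3% against 1.78% for Cthrc1).

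**Figure D3:**
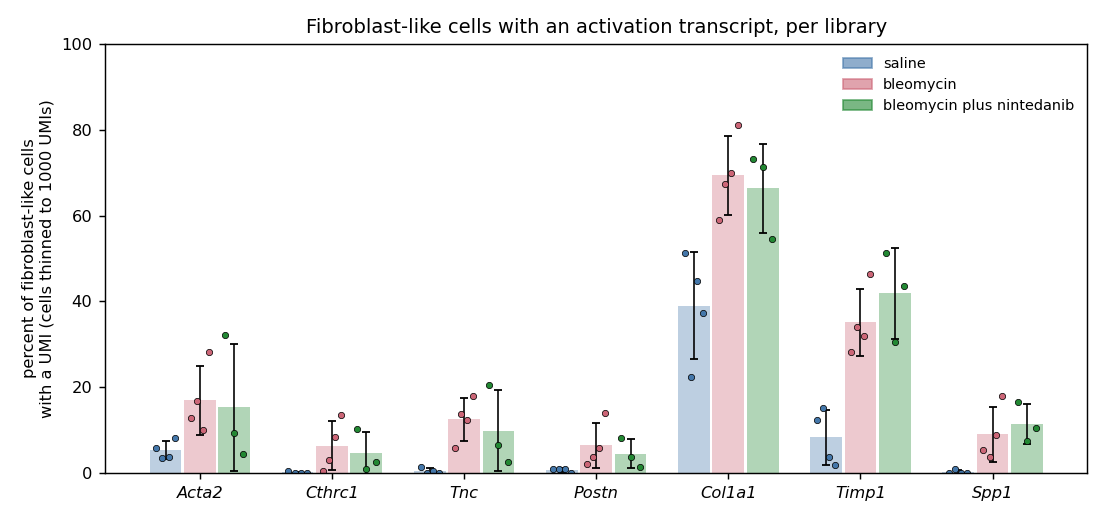
Percent of fibroblast-like cells, thinned to 1000 UMIs, with at least 1 UMI of each of 7 transcripts, with points for libraries, bars for group means and error bars for the SD. For Tnc the bleomycin mean is 12.5% and the saline mean 0.447%, with 9.84% for nintedanib.

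Cells with Cthrc1 were compared with other fibroblast-like cells of the same library for Acta2. In the 4 bleomycin-treated libraries with at least 5 thinned Cthrc1-positive cells, Acta2 was seen in 38.2% ± 35 of them and 16.2% ± 11.1 of the rest (SD, n = 4). The mean difference was 22.0 percentage points, positive in 3 of 4 libraries and −4.57 in nintedanib replicate 3, with p = 0.25 in the exact sign-flip permutation test, whose smallest p was 0.125. Without nintedanib replicate 1 it was 11.6 points.

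The effect of nintedanib on fibroblast-like cells was tested against bleomycin alone. Col1a1 stood at 2020 ± 886 CPM (SD, n = 3) against 2820 (log2 fold change −0.48, SE 0.33), Ctgf at 42.2 against 102 CPM (−1.30, SE 0.57), Cthrc1 at −0.76, Tnc at −0.59, Postn at −0.02, Acta2 at 0.47, Spp1 at 0.15 and Timp1 at −0.22 on the log2 scale. Igfbp3 was at 39.5 ± 28.6 against 14.3 CPM (1.48, SE 0.38, unadjusted p = 0.00197), and Pdgfra, Pdgfrb, Fgfr1 and Tgfb1 were at 0.34, −0.26, 0.16 and −0.46. None of these passed, each at an edgeR adjusted p of 0.999. Of all genes edgeR called 0, with 275 at an unadjusted p under 0.05, and DESeq2 called 1. Interferon response genes lay lower as a group, 2 of 23 above bleomycin (camera adjusted p = 0.000574, and adjusted p = 0.772 with an estimated correlation). That camera result was lost without bleomycin replicate 1 (8 of 22 higher, adjusted p = 0.122) or nintedanib replicate 3 (6 of 23, adjusted p = 0.181). Lower too by camera were the p53 (2 of 15 higher, adjusted p = 0.0144), matrix (5 of 28 higher, 0.0273) and contractile lists (0.0273), and glycolysis was higher (0.0183). With an estimated correlation these gave adjusted p = 0.453, 0.772, 0.772 and 0.765. The PDGF, FGF and VEGF list gave a camera adjusted p = 0.72, and no member of any list was called. Fry passed for 0 of the 14 lists, in one direction or in either. Set A holds 1 nintedanib library, replicate 1, so its values are those of a single library. In sets A and B, Cthrc1 was at 1.80 and −3.25, Acta2 at 2.29 and −1.33, Tnc at 1.04 and −2.51, and Col1a1 at 0.44 and −1.13.

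Fibroblast-like cells of nintedanib-treated lungs were also compared with saline. Ltbp2 rose from 13.1 to 325 CPM (4.50, SE 0.51, edgeR adjusted p = 0.00498) and Ecscr, a gene best known from endothelial cells, from 6.46 to 82.7 CPM (3.54, SE 0.46, adjusted p = 0.00803), both in 7 of 7 fits that left out 1 library. Col1a1 (1.45, adjusted p = 0.0568), Cthrc1 (4.14, adjusted p = 0.0991) and Postn (4.11, adjusted p = 0.0582) were not called. EdgeR called 106 genes, 74 higher and 32 lower, and DESeq2 349. The count was 11 without nintedanib replicate 1, 22 without saline replicate 1, 215 without saline replicate 2, and 7 and 9 without saline replicates 3 and 4. Of 15 p53 targets 3 rose (8 adjusted over the list alone; camera adjusted p = 5.8e-07, and adjusted p = 0.0295 with an estimated correlation), and of 28 matrix genes 9 rose (19 adjusted over the list alone; camera adjusted p = 6.22e-13, and adjusted p = 0.311 with an estimated correlation). Camera passed for 9 of 14 lists in this comparison, and the p53 list alone held with an estimated correlation. A gene called against saline with bleomycin and not with nintedanib is not thereby shown to differ between the treatments.

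**Figure D4:**
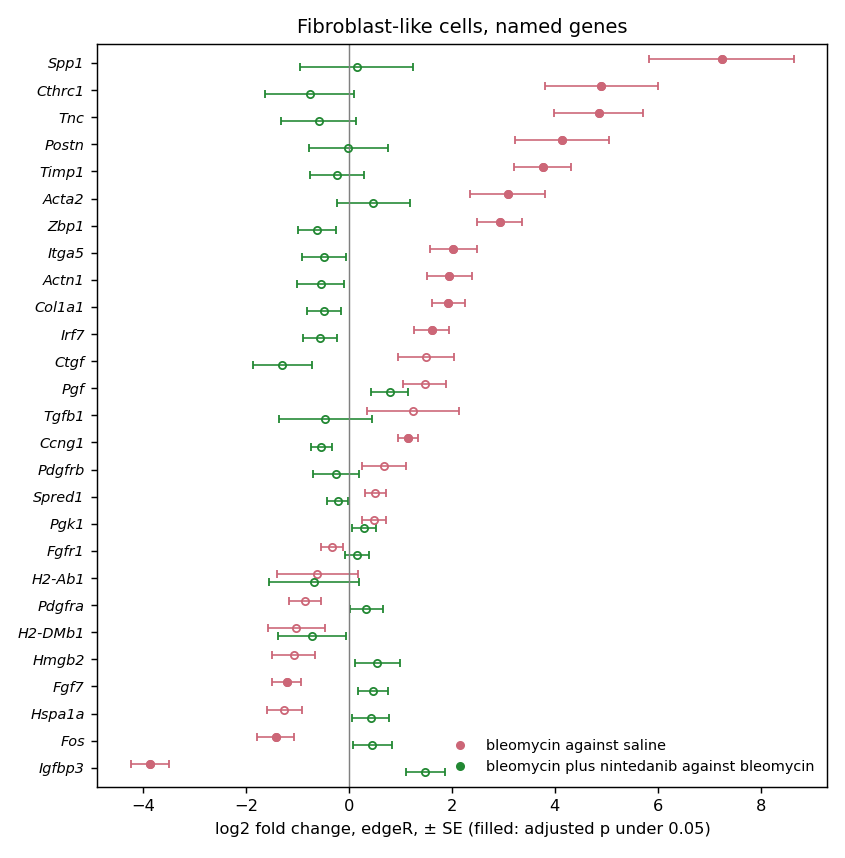
Log2 fold change with its SE (edgeR) of 27 genes in fibroblast-like cells, for bleomycin against saline and for nintedanib against bleomycin, with filled points where the adjusted p was under 0.05. No gene is filled in the second comparison, where Col1a1 lies at −0.48.

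In alveolar macrophage-like cells bleomycin raised genes of the fibrosis-associated macrophage list and lowered genes of the resident state. Trem2, a lipid-sensing receptor, rose from 90.1 ± 16.5 to 336 ± 61.4 CPM (SD, n = 4 each, log2 fold change 1.85, SE 0.24, edgeR adjusted p = 0.00122), Spp1 from 338 ± 337 to 4010 ± 2310 (3.41, SE 0.58, adjusted p = 0.00633) and Fn1 from 146 ± 111 to 1150 ± 479 (2.95, SE 0.45). The secretory kinase gene Fam20c (0.341 to 65.4 ± 25.4 CPM, adjusted p = 0.000392), seen in 1 saline library and at the level of a single UMI, and S100a4 (24.3 ± 20.7 to 339 ± 115 CPM, 3.73, SE 0.51) rose, while Krt79 (302 ± 203 to 18.8 ± 19.9 CPM, −4.50, SE 0.61) and galanin Gal (−2.72, SE 0.46) fell. Each of these 7 was called in all 8 fits that left out 1 library. Mmp14, a membrane metalloproteinase, had no counts in saline and 52.8 ± 6.70 CPM with bleomycin, at least 22.3-fold higher against 3 counts over the saline group; its call was lost without saline replicate 1 (fitted log2 fold changes 7.42 to 7.65). Marco, a scavenger receptor, fell from 465 ± 156 to 105 ± 63.3 CPM (−2.16, SE 0.41; lost without bleomycin replicate 2), and the lipid droplet gene Cidec by 2.42 on the log2 scale (lost without bleomycin replicate 4). Over the fits Marco stayed between −2.74 and −1.84 and Cidec between −2.87 and −1.84. Sets A and B alone gave 1.83 and 1.87 for Trem2, 2.28 and 4.46 for Spp1, 4.37 and 2.49 for Fn1, 4.21 and 3.39 for S100a4, −3.16 and −5.22 for Krt79, −1.31 and −3.90 for Gal, −2.71 and −1.65 for Marco and −1.52 and −2.91 for Cidec. Spp1, Gal and Cidec lost their calls in set A, and Marco and Mmp14 in set B.

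Of 22 fibrosis-associated genes 7 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000463, and adjusted p = 0.152 with an estimated correlation). Of 14 homeostasis genes 4 fell (8 adjusted over the list alone), with none of the 14 higher (camera adjusted p = 2.57e-08, and adjusted p = 0.00982 with an estimated correlation). Of 16 lipid handling genes 1 fell, the fatty acid transporter Cd36 (1 adjusted over the list alone; camera adjusted p = 0.904); it lost its call without saline replicate 1 or bleomycin replicate 1, 2 or 4 (−3.25 to −1.92). No member of the interferon, MHC class II or glycolysis lists was called (2 interferon genes higher and none of the other lists adjusted over the list alone), with camera adjusted p = 0.0129, 0.00262 and 0.0306 toward higher levels and adjusted p = 0.289, 0.39 and 0.152 with an estimated correlation. Of the genes tested (4839), 103 were called, 59 higher and 44 lower. The count was 67 without bleomycin replicate 1, 40, 42 and 26 without replicates 2, 3 and 4, 54 without saline replicate 1 and 62 without saline replicate 4. It was 249 within set A and 57 within set B.

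Trem2 and Spp1 also rose in interstitial or monocyte-derived macrophage-like cells. Trem2 went from 227 ± 72.2 to 778 ± 99.3 CPM (SD, n = 4 each, 1.78, SE 0.23, edgeR adjusted p = 0.00664) and was called in all 8 fits that left out 1 library. Spp1 rose from 124 ± 160 to 4540 ± 1050 CPM (5.11, SE 0.85, adjusted p = 0.023; lost without saline replicate 3 or 4 or bleomycin replicate 3 or 4, 4.73 to 6.48). Il1rn, the interleukin 1 receptor antagonist, rose from 13.1 ± 4.97 to 133 ± 36.9 CPM (3.33, SE 0.54), the fungal beta-glucan receptor gene Clec7a by a log2 fold change of 2.27 (SE 0.40) and Isg15 by 3.12 (SE 0.57). Pltp, a phospholipid transfer protein gene, fell from 579 ± 166 to 215 ± 40.4 CPM (−1.43, SE 0.23). These 4 lost their calls without saline replicate 1, 3 or 4 or bleomycin replicate 3 or 4, and Clec7a also without bleomycin replicate 1. Over the fits the log2 fold change stayed between 3.12 and 3.58 for Il1rn, 2.07 and 2.47 for Clec7a, 2.64 and 3.39 for Isg15 and −1.54 and −1.21 for Pltp. In sets A and B alone it was 1.63 and 1.95 for Trem2, 3.93 and 9.70 for Spp1, 3.23 and 3.33 for Il1rn, 2.09 and 2.40 for Clec7a, 4.04 and 2.05 for Isg15 and −0.99 and −1.87 for Pltp. Of these Spp1 alone was called in set A, and Clec7a and Isg15 were not called in set B. Pooled over libraries, these values compare saline cells mostly of the Ccl8 and Folr2 cluster with bleomycin cells mostly of the Gpnmb and Spp1 cluster and of one led by Ccr2, Mmp12 and Ccl9.

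Of 24 fibrosis-associated genes 4 rose in these cells (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.54e-12, and adjusted p = 0.00822 with an estimated correlation). Of 24 interferon response genes 1 rose (9 adjusted over the list alone; adjusted p = 1.3e-06, and adjusted p = 0.259 with an estimated correlation). Without bleomycin replicate 1, which stood apart for Isg15 (92.5 CPM against at most 35.5), 21 of 24 were higher (camera adjusted p = 3.39e-06, and adjusted p = 0.211 with an estimated correlation). None of 19 immediate early genes was called (14 lower adjusted over the list alone; adjusted p = 2.26e-09, and adjusted p = 0.222 with an estimated correlation). EdgeR called 52 genes of those tested (9430), 36 higher and 16 lower, and DESeq2 416. Without 1 library the count was 29, 190, 3 and 3 (bleomycin replicates 1 to 4) and 11, 293, 9 and 3 (saline replicates 1 to 4), and within sets it was 1 in A and 217 in B.

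In vascular endothelial-like cells bleomycin raised genes of the endothelial activation list, and the capillary genes Car4 and Ednrb fell. Sparcl1, a matricellular protein gene, rose from 87.5 ± 26.7 to 482 ± 152 CPM (SD, n = 4 each, 2.40, SE 0.29, edgeR adjusted p = 0.00893) and Ankrd37, a hypoxia-inducible gene, from 21.6 ± 16.7 to 240 ± 48.1 (3.20, SE 0.41, adjusted p = 0.00993). Sparc rose from 296 ± 77.6 to 1260 ± 308 CPM (2.07, SE 0.29) and Cmah by a log2 fold change of 4.15 (SE 0.68). Car4, the carbonic anhydrase of lung capillaries, fell from 1360 ± 254 to 678 ± 146 CPM (−1.0, SE 0.18), Ednrb, an endothelin receptor, from 314 ± 77.3 to 102 ± 41.0 (−1.61, SE 0.29) and Cyp4b1 from 918 ± 174 to 356 ± 104 (−1.38, SE 0.23). No named gene held its call in all 8 fits that left out 1 library. All lost it without saline replicate 3 or 4, where edgeR called 0 genes. Sparc lost it also without bleomycin replicate 2 or 4, Cmah without those or saline replicate 1, Car4 and Cyp4b1 without bleomycin replicate 2, 3 or 4 or saline replicate 1, and Ednrb without bleomycin replicate 1, 2 or 4 or saline replicate 1. Over the fits the values stayed between 2.15 and 2.50 for Sparcl1, 3.01 and 3.62 for Ankrd37, 1.92 and 2.24 for Sparc, 3.83 and 4.97 for Cmah, −1.12 and −0.89 for Car4, −1.90 and −1.44 for Ednrb and −1.53 and −1.20 for Cyp4b1. Set A alone and set B alone gave 2.24 and 2.50 for Sparcl1, 2.97 and 3.39 for Ankrd37, 1.89 and 2.24 for Sparc, 3.48 and 4.98 for Cmah, −1.15 and −0.82 for Car4, −1.98 and −1.27 for Ednrb and −1.05 and −1.71 for Cyp4b1, with no call in set A and those of Sparcl1 and Sparc kept in set B. Car4 and Cyp4b1 were among the leading genes of the cluster that held a smaller part of the class in bleomycin libraries, so these values compare mixtures of clusters.

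Of 16 endothelial activation genes 4 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.17e-07, and adjusted p = 0.0161 with an estimated correlation). Of 16 capillary identity genes Car4 and Ednrb fell (1 higher and 6 lower adjusted over the list alone; adjusted p = 2.27e-05, and adjusted p = 0.0565 with an estimated correlation). No tip cell gene of 10 was called (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.863). Of 10 PDGF, FGF and VEGF receptors and ligands none was called, also adjusted over the list alone (camera adjusted p = 0.756), and of 10 MAP kinase feedback genes Dusp6 rose (1.24, SE 0.24; 1 adjusted over the list alone; adjusted p = 0.0723). Dusp6 kept its call only without saline replicate 1 (1.1 to 1.5 over the fits). EdgeR called 36 genes of those tested (7553), 25 higher and 11 lower, and DESeq2 86. Without 1 library the count was 15, 4, 15 and 3 (bleomycin replicates 1 to 4), 10 and 50 (saline replicates 1 and 2) and 0 (saline replicates 3 and 4). Within sets it was 0 in A and 6 in B.

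In alveolar type 2-like cells p53 targets rose with bleomycin. Ccng1 rose from 29.6 ± 7.14 to 286 ± 44.6 CPM (SD, n = 4 each, 3.28, SE 0.22, edgeR adjusted p = 6.82e-06), Phlda3 from 6.86 ± 6.15 to 131 ± 49.5 (3.91, SE 0.40, adjusted p = 0.000388), Bax from 79.0 ± 8.66 to 260 ± 79.9 (1.70, SE 0.21) and Rps27l from 406 ± 40.2 to 1100 ± 177 (1.43, SE 0.16). Isg15, an interferon-induced ubiquitin-like protein gene, rose from 4.48 ± 2.38 to 61.7 ± 32.7 CPM (3.86, SE 0.47), the growth factor gene Hbegf from 13.3 ± 3.54 to 91.6 ± 35.3 (2.77, SE 0.31) and Itm2a by 3.39 on the log2 scale (SE 0.53). Aox3, an aldehyde oxidase gene, fell from 96.6 ± 21.4 to 17.0 ± 10.4 CPM (−2.46, SE 0.36), and Fgfbp1 by 2.40 (SE 0.39). Tyrobp, a signalling adaptor of myeloid cells and not an epithelial gene, fell from 110 ± 39.0 to 23.8 ± 10.4 CPM (−2.11, SE 0.37). Each of these genes was called in all 8 fits that left out 1 library. Within sets A and B the values were 3.06 and 3.48 for Ccng1, 3.42 and 4.27 for Phlda3, 1.79 and 1.58 for Bax, 1.52 and 1.33 for Rps27l, 3.79 and 3.76 for Isg15, 2.17 and 3.28 for Hbegf, 2.06 and 4.87 for Itm2a, −1.71 and −3.20 for Aox3, −1.89 and −2.93 for Fgfbp1 and −2.32 and −1.93 for Tyrobp. Of these only Ccng1, Rps27l and Isg15 were called in set A, and Tyrobp was not called in set B.

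Of 16 p53 targets 8 rose (13 adjusted over the list alone; camera adjusted p = 1.41e-13, and adjusted p = 0.00619 with an estimated correlation), and of 14 interferon response genes 6 rose (9 adjusted over the list alone; adjusted p = 1.22e-06, and adjusted p = 0.00619 with an estimated correlation). Of 18 lipid handling genes 4 fell (6 adjusted over the list alone), among them the sterol sensor partner Insig1, Lpl and the fatty acid synthesis gene Acaca (adjusted p = 0.00105, and adjusted p = 0.17 with an estimated correlation). The calls of these 3 depended on single libraries. Insig1 (−1.12 to −0.91) was lost without saline replicate 3 or 4 or bleomycin replicate 2 or 3, Lpl (−2.21 to −1.65) without those saline replicates or bleomycin replicate 3 or 4, and Acaca (−0.94 to −0.70) without those saline replicates or any bleomycin replicate. Of 17 transitional epithelial genes 3 rose (5 adjusted over the list alone; adjusted p = 1.32e-05, and adjusted p = 0.266 with an estimated correlation), and 4 of 19 immediate early genes fell (12 adjusted over the list alone; adjusted p = 1.22e-06, and adjusted p = 0.162 with an estimated correlation). None of 13 surfactant genes was called (1 lower adjusted over the list alone; camera adjusted p = 0.656). EdgeR called 254 genes of those tested (6733), 140 higher and 114 lower. The count was 119, 70, 44 and 72 without bleomycin replicates 1 to 4, 414 without saline replicate 2, and 49 and 51 without saline replicates 3 and 4. It was 3 within set A and 160 within set B.

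Nintedanib against bleomycin gave few calls in these 4 classes. EdgeR called 0 genes in alveolar macrophage-like cells (110 at an unadjusted p under 0.05, DESeq2 0), 0 in interstitial or monocyte-derived macrophage-like cells (198, DESeq2 0) and 0 in vascular endothelial-like cells (191, DESeq2 0). In alveolar type 2-like cells, with 2 nintedanib libraries large enough, it called Cybb (1.79 to 56.8 CPM, 4.65, SE 0.69) and Fcer1g (13.6 to 109 CPM, 2.87, SE 0.40), both at an adjusted p of 0.0369, and DESeq2 called 11. Both are myeloid genes. Their calls were lost without any of the 4 bleomycin libraries or without nintedanib replicate 2, which left 1 nintedanib library. Interferon response genes lay lower in interstitial or monocyte-derived macrophage-like cells, with 1 of 24 higher (camera adjusted p = 1.02e-14, and adjusted p = 0.167 with an estimated correlation), and in vascular endothelial-like cells, with 2 of 22 higher (adjusted p = 3.8e-05, and adjusted p = 0.685 with an estimated correlation). Without bleomycin replicate 1 the former stayed (1 of 24 higher, camera adjusted p = 1.21e-11, and adjusted p = 0.101 with an estimated correlation) and the latter did not (7 of 21 higher, adjusted p = 0.0851). Leaving out nintedanib replicate 3 also removed the vascular result (adjusted p = 0.069). Camera did not pass for them in alveolar type 2-like (8 of 14 higher, adjusted p = 0.783) or alveolar macrophage-like cells (2 of 6 higher, adjusted p = 0.416). MHC class II genes lay lower by camera in interstitial or monocyte-derived macrophage-like (0 of 7 higher, adjusted p = 1.56e-05, and adjusted p = 0.373 with an estimated correlation) and alveolar macrophage-like cells (0 of 6, adjusted p = 0.0195, and adjusted p = 0.441 with an estimated correlation), and so did fibrosis-associated genes in the latter (8 of 22, adjusted p = 0.0496, and adjusted p = 0.441 with an estimated correlation). Higher by camera were glycolysis genes in interstitial or monocyte-derived macrophage-like cells (13 of 14, adjusted p = 0.00424, and adjusted p = 0.578 with an estimated correlation). So were inflammatory mediators in alveolar macrophage-like (7 of 9, adjusted p = 0.0125, and adjusted p = 0.106 with an estimated correlation) and alveolar type 2-like cells (7 of 10, adjusted p = 0.0178, and adjusted p = 0.55 with an estimated correlation), and immediate early genes in the same 2 classes (10 of 16, adjusted p = 0.0316, and adjusted p = 0.441 with an estimated correlation; 16 of 19, adjusted p = 0.000873, and adjusted p = 0.55 with an estimated correlation). No member of any list was called, and adjusted over the list alone only 1 member of these lists was, an inflammatory mediator in alveolar macrophage-like cells, higher. No camera call in this comparison held with an estimated correlation. Fry passed for 0 lists in each of these 4 classes, in one direction or in either.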

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

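The tests of depth and GC content, of blood, swapped labels and free RNA, of the shared bleomycin libraries and of other splits were chosen only after the result was seen; the test of the 72 genes in alveolar type 1-like and mesothelial-like cells was written before.

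The first pattern was that 72 genes lay lower in 5 of the 11 libraries in each class scored. The difference between the sets, taken in alveolar type 1-like and mesothelial-like cells, which had not been used to find the genes, correlated over 65 genes at r = 0.875 (across genes, which are not independent replicates), as a difference in library preparation or read processing would give. Depth is argued against, since 2 libraries of the higher set had fewer UMIs than the deepest library of the lower set. GC content is argued against by genes matched on GC content and level, which differed by a median of 0.17 in T-like cells where 57 of the 72 genes with a match differed by 1.80. A difference in preparation or processing may thus account for the pattern and stays open, the labels give no batch, and no biological explanation was tested.

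The second pattern was neutrophil-like cells and acute-phase transcripts in saline replicate 2 and nintedanib replicate 3. Blood carried over stays open for the neutrophil-like cells of saline replicate 2, whose haemoglobin transcripts stood at 5234 CPM of the library against at most 1847 in the 9 libraries outside the pattern. Cell shares do not point to it. Saline replicate 1, at 1847 CPM, had 0.69% neutrophil-like cells. B-like and monocyte-like cells made up 0.75% and 0.273% of saline replicate 2, the lowest of the saline libraries. Blood is argued against in nintedanib replicate 3, where haemoglobin transcripts stood at 6.14 CPM. Exchanged labels are argued against, since interstitial or monocyte-derived macrophage-like cells made up 22.3% of nintedanib replicate 3 and at most 6.56% of a saline library. Free RNA is argued against for the acute-phase transcripts, whose summed CPM rose at least 6.07 times as far in vascular endothelial-like as in T-like cells. No biological explanation was tested for either library.

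The third pattern was that bleomycin-called fibroblast-like genes took the opposite sign under nintedanib, where no gene was called. With all bleomycin libraries in both comparisons 78.2% of the called genes did so, but simulated counts with no nintedanib effect gave 64.6%, as both comparisons share those libraries. With the bleomycin libraries split between the comparisons the share was 56.9% on average over 6 splits (42.6% to 66.7%) against 50% simulated. The splits called 86 genes on average and the simulated ones 631, so the spread of the simulated shares does not show that expected of the smaller set. Shares in alveolar macrophage-like cells were 56.3% unsplit against 66.5% simulated and 47.7% split against 50.2%. The fibroblast-like covariance of the fold changes was −0.126 unsplit and −0.0684 split, against −0.0670 and −0.00306 simulated. A partial reversal by nintedanib and the shared libraries cannot be told apart here, because some splits lay below the simulated share.

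Other splits of the same libraries were counted for each count of genes, 35 in each comparison. For bleomycin against saline only the real split, 1 of 35, called as many genes in fibroblast-like (362, highest other 0), alveolar macrophage-like (103, highest other 6), alveolar type 2-like (254, highest other 46) and vascular endothelial-like cells (36, highest other 13). That is the smallest share 35 splits can give, and it was not adjusted over the classes. It argues against chance in these classes but cannot exclude it. In vascular endothelial-like cells the count also fell to 0 without saline replicate 3. In interstitial or monocyte-derived macrophage-like cells 2 of 35 splits reached 52, with 81 for the other, and chance cannot be excluded. For nintedanib against saline in fibroblast-like cells 2 of 35 reached 106, with 166 for the other, and chance cannot be excluded. For nintedanib against bleomycin splits cannot test a real count of 0, which every split meets. In that comparison the split that set bleomycin replicates 1 and 2 and nintedanib replicate 1 against the rest called 162 genes in fibroblast-like, 168 in interstitial or monocyte-derived macrophage-like, 226 in vascular endothelial-like and 9 in alveolar macrophage-like cells, which points to a structure of the samples. The library sets were drawn from this split in the first 3 of these classes, so these counts do not support the sets.

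Single libraries far from the others of their saline or bleomycin group are given as values, nintedanib ones not being tested. Of 296 groups 32 had one. The 14.8 by chance cannot be compared, as levels seen in 1 library alone always count. Neutrophil-like cells made up 31.4% of saline replicate 2 (at most 0.69% in the others), natural killer-like cells 3.06% of saline replicate 1 (at most 1.57%) and club or secretory-like cells 1.1% of saline replicate 3 (at most 0.444%). Among thinned fibroblast-like cells, Cthrc1 was seen in 0.439% in saline replicate 1 and Spp1 in 0.893% in saline replicate 2, with 0 in the other saline libraries, and Postn in 0 in saline replicate 4 (at least 0.877% in the others).

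In fibroblast-like cells, saline replicate 1 stood high for Col1a1 (972 CPM) and Ltbp2 (26.2), saline replicate 2 for Spp1 (102), Tsc22d3 (1750), Txnip (1284) and Zbp1 (28.4), and saline replicate 4 for Nr4a1 (684 CPM). Bleomycin replicate 1 stood high for Fgf7 (115 CPM), Irf7 (118) and Zbp1 (102), and bleomycin replicate 4 for Wisp1 (195). In alveolar macrophage-like cells these were Arg1 in saline replicate 4 (5.11 CPM), Fam20c and Slc39a2 in saline replicate 1 (1.36 and 685) and Fabp1 in bleomycin replicate 1 (67.4). In alveolar type 2-like cells saline replicate 1 stood high for Bax (91.9 CPM), Fxyd4 (6.13) and Itm2a (36.8), bleomycin replicate 1 for Fosb (43.3), and bleomycin replicate 3 for Junb (181) and Phlda3 (205). In interstitial or monocyte-derived macrophage-like cells Isg15 was at 92.5 CPM in bleomycin replicate 1. In vascular endothelial-like cells saline replicate 1 stood high for Ifitm3 (2530 CPM) and Ntrk2 (52.1), and saline replicate 2 high for Ednrb (429) and low for Sparcl1 (47.7).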

How the results depend on the processing

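The alternatives with the library sets, without the libraries with many neutrophils and with another naming pseudocount were chosen only after the data were seen; the others were fixed before. Each changed 1 choice, except the library set as a covariate without the libraries with many neutrophils, which changed 2. Of 3680 values for 156 called results of the naming rule 2748 stayed past the threshold and 932 did not. None changed sign, which its demand for no overlap largely ensures. Of 10615 values for 448 results not called, 10016 stayed so, 307 passed and 292 changed sign without a call. The shares whose sign changed differed by less than the SD between libraries as first computed. The number of calls moved widely, and unless the setting itself tests fewer libraries or other genes the cause was not tested.

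Bleomycin against saline, calls in fibroblast-like cells numbered 362, and 737 with DESeq2, 582 without the libraries with many neutrophils, 812 without them and with the library set as a covariate, 575 with only the groups compared, 197 with the replicate block, 6 within library set A and 221 within set B. In alveolar macrophage-like cells (103) they numbered 194 at Leiden resolution 2, 157 with no doublet removal, 366 with no low-count filter, 63 with only the groups compared, 46 with the replicate block, 189 with the stricter cell filter, 251 with the title number series, 249 in set A and 57 in set B. In interstitial or monocyte-derived macrophage-like cells (52) they were 416 with DESeq2, 102 at Leiden resolution 2, 355 without the neutrophil-rich libraries, 428 with the set covariate too, 25 at a naming pseudocount of 10 CPM, 86 with no doublet removal, 256 with no low-count filter, 127 with only the groups compared, 16 with the block, 28 with the title number series, 1 in set A and 217 in set B. In vascular endothelial-like cells (36) they were 86 with DESeq2, 94 without the neutrophil-rich libraries, 59 with the set covariate, 355 with both, 20 at a naming pseudocount of 100 CPM, 70 with no low-count filter, 13 with the block, 12 with the stricter filter, 0 in set A and 6 in set B. In alveolar type 2-like cells (254) they were 72 with at least 30 cells, 520 without the neutrophil-rich libraries, 639 with the set covariate too, 680 with no low-count filter, 91 with the block, 152 with the title number series, 3 in set A and 160 in set B.

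Nintedanib against bleomycin, DESeq2 called 1 gene in fibroblast-like cells where edgeR called 0. In alveolar macrophage-like cells 41 were called with no low-count filter. In alveolar type 2-like cells (2) the calls were 11 with DESeq2, 5 at Leiden resolution 2, 0 with at least 30 cells, 0 with the free RNA filter, 0 with no doublet removal, 24 without the neutrophil-rich libraries, 4 with the set covariate, 21 with both (the 24 and the 21 with 1 nintedanib library), 123 with no low-count filter, 8 with only the groups compared, 1 with the block, 5 with the stricter filter, 4 with the title number series and 1 in set B. Nintedanib against saline in fibroblast-like cells gave 106, and 349 with DESeq2, 265 with the set covariate and without the neutrophil-rich libraries, 15 with the block, 68 in set A, with 1 nintedanib library and a spread taken from the other groups, and 27 in set B.

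Differences in shares changed sign, in percentage points, for alveolar macrophage-like cells as a percent of the same compartment (−0.187), fibroblast-like cells at Leiden resolution 2 (−0.482) and without the neutrophil-rich libraries (−0.840) and vascular endothelial-like cells at a naming pseudocount of 100 CPM (−0.0452), bleomycin against saline. Nintedanib against bleomycin they did so for alveolar type 2-like cells within their compartment (0.275), for interstitial or monocyte-derived macrophage-like cells with the block (0.378) and without the neutrophil-rich libraries (0.108), and for vascular endothelial-like cells without them (0.157). Of the 7 activation transcripts 0 passed with the block and 0 without the neutrophil-rich libraries, designs too small to pass. The Acta2 difference by Cthrc1 passed without thinning (33.0 points), where deeper cells can show both transcripts more often, and with Tnc in place of Cthrc1 (12.5). The opposite-sign share was 78.2% unsplit, and of the 45 list tests past the threshold for bleomycin against saline and nintedanib against bleomycin 6 held with an estimated correlation, all in the first comparison.

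Leaving out 1 library at a time, calls for bleomycin against saline ran from 68 to 323 in fibroblast-like, 26 to 151 in alveolar macrophage-like, 3 to 293 in interstitial or monocyte-derived macrophage-like, 0 to 50 in vascular endothelial-like and 44 to 414 in alveolar type 2-like cells. For nintedanib against bleomycin they ran from 0 to 0, 0 to 2, 0 to 0, 0 to 0 and 0 to 10 (the 10 in a fit left with 1 nintedanib library), and against saline in fibroblast-like cells from 7 to 215. Share differences for bleomycin against saline ran from −0.840 to 1.46 (fibroblast-like), 0.266 to 2.21 (alveolar macrophage-like), 19.7 to 26.7 (interstitial or monocyte-derived macrophage-like), 0.167 to 3.52 (vascular endothelial-like) and −10.1 to −4.81 (alveolar type 2-like). For nintedanib against bleomycin they ran from −2.95 to 0.630, 0.617 to 3.36, −5.69 to 1.34, −3.04 to 0.157 and −0.489 to 0.334, in the same order. Activation transcripts passing numbered 0 to 0, as 4 against 3 libraries allow no p under 0.0571, and the Acta2 difference ran from 11.6 to 30.9 points. Lists past the camera threshold, 45 in the main fit, ran from 39 (without bleomycin replicate 1) to 50, an alternative chosen after seeing the results. Of the 6 held with an estimated correlation, camera lost the interferon list of alveolar type 2-like cells without nintedanib replicate 2 (adjusted p = 0.0628) and the activation list of vascular endothelial-like cells without saline replicate 1 (adjusted p = 0.0571). Replicate numbers did not pair the libraries: 5 of 10 same-number pairs had a correlation above 0.1 (−0.437 to 0.385), and 3 of 11 libraries were closest to one of their own number. Bleomycin against saline, 24.5% of simulated 2-fold changes in fibroblast-like cells were recovered, with fewer likely for genes that vary more.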

Other observations

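The gene counts and genes of the classes below follow the rule fixed before the data were examined, while the look at acute-phase and haemoglobin transcripts was chosen only after the result was seen; leaving out single libraries was not run in these classes. Alveolar type 1-like cells had the most called genes of any class with bleomycin (edgeR 796, 364 higher, 432 lower, n = 4 against 4). The leukocyte gene Ptprc was seen in 21.8% of them, so they may be a mixture. Sprr1a, a cornified envelope gene, rose from 0.996 ± 1.99 to 590 ± 602 CPM (SD, adjusted p = 0.0107), the saline level being that of single UMIs. Anxa8 and Ddit4l had no counts in saline and 55.4 ± 38.8 and 50.6 ± 19.2 CPM with bleomycin, at least 14.2-fold and 13.0-fold higher against 3 counts over the saline group. Gsta3, a glutathione transferase gene, fell from 526 ± 364 to 40.9 ± 23.3 CPM (−3.73, SE 0.65, adjusted p = 0.00332) and Gpr155 by 3.91 on the log2 scale (SE 0.78). Igfbp6 fell from 5610 ± 7390 to 123 ± 98.0 CPM (−5.58, SE 1.07). It is a leading gene of the mesothelial-like clusters, 4.55% ± 1.75 of saline and 2.10% ± 1.28 of bleomycin libraries.

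Among the genes called with bleomycin in T-like cells, Foxp3, the transcription factor of regulatory T cells, rose from 8.72 ± 6.69 to 76.2 ± 38.0 CPM (SD, n = 4 each, 3.01, SE 0.48, edgeR adjusted p = 0.0133) and Tnfrsf4, a costimulatory receptor gene, from 33.4 ± 15.3 to 362 ± 134 CPM (3.5, SE 0.40, adjusted p = 0.000983). A cluster led by Tnfrsf4, Cxcr6 and Gata3 held 12.2% to 27.6% of the class in the saline and 24.3% to 53.9% in the bleomycin libraries. In monocyte-like cells Cxcl16 rose from 4.91 to 236 CPM (5.63, SE 0.98, adjusted p = 0.0302), while Spn fell from 197 ± 16.1 to 50.4 ± 22.0 CPM (−1.92, SE 0.33). In type 1 conventional dendritic-like cells the interferon regulatory factor gene Irf7 rose from 9.62 to 103 CPM (3.36, SE 0.46, adjusted p = 0.0062) and Timd4 fell from 59.1 to 4.39 CPM (−3.76, SE 0.39). In type 2 ones the lectin gene Clec4n rose from 17.6 ± 6.36 to 394 ± 123 CPM (4.39, SE 0.38, adjusted p = 4.94e-05). Trem2 rose in proliferating cells from 6.74 ± 6.06 to 222 ± 23.8 CPM (4.84, SE 0.42, adjusted p = 0.00027). Fcgr1, with no saline counts, rose at least 8.56-fold. This class pools dividing cells, so mixtures may differ. Calls numbered 22 in T-like, 24 in monocyte-like, 35 in type 1 and 7 in type 2 conventional dendritic-like and 5 in proliferating cells. EdgeR called 0 genes in B-like (151 at an unadjusted p under 0.05), natural killer-like (73), mesothelial-like (285) and smooth muscle or pericyte-like cells (71). Mature dendritic-like cells had 1 saline library, too few to compare. No other tool was run in these classes. Nintedanib against bleomycin gave 0 edgeR calls in each, with 35 (natural killer-like) to 389 (mesothelial-like) at an unadjusted p under 0.05.

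Haemoglobin transcripts stood at 731 to 5234 CPM of the whole library in the saline libraries and 3.04 to 269 in the bleomycin libraries, without overlap. In the nintedanib libraries they stood at 3.54, 1553 and 6.14. Summed over 8 acute-phase genes, fibroblast-like cells of saline replicate 2 and nintedanib replicate 3 held 27390 and 52490 CPM, and those of the other libraries 949 to 10210 CPM. Construct sequences in the reference stood at 1.56, 1.6 and 1.16 CPM in saline, bleomycin and nintedanib libraries.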
